A study of Mus musculus with 12 samples.

How the data were processed

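The 12 libraries were prepared, per the labels' protocols, from column-purified total RNA with a stranded total RNA kit after ribosomal RNA removal. Per the submitters' processing notes, the tools used were CASAVA 1.8.2, FastQC 0.11.3, STAR 2.4.1d, featureCounts 1.4.6 and DESeq2 1.6.3, with the builds mm10 and GRCm38.p4. The annotation release and the strand setting of the counting are not given in the sources used here, so reads of overlapping and antisense genes may not be told apart. The authors deposited a table of raw counts, whole numbers for 39179 Ensembl genes in each library, and a table of TPM values with gene symbols and biotypes. These TPM values are a normalised signal made by the authors and used as deposited. How they were made is not described beyond the unit, and what follows was inferred from the values.

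The deposited TPM values were checked against the counts: they equal (count + 1) divided by 1 length per gene and scaled per library, to within rounding. They sum to the same total in every library over 38310 unique genes, and 722 of 39032 entries repeat a gene for another identifier. Each gene was used once, and 869 counted genes were absent from the TPM table. Symbols came from that table for 38104 genes, and 1075 genes had none and keep their identifier. Coordinates, exon lengths and GC content came from the GENCODE M21 annotation of GRCm38 (mm10 coordinates), which holds 37607 of the counted genes, and are 1-based. Library totals were between 25862573 and 37319846 counts.

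Groups and replicate numbers came from the sample titles. The main test was edgeR 4.0.16 (R 4.3.3) with the quasi-likelihood fit on the counts as deposited, TMM scaling and edgeR's expression filter by group (minimum count 10, total 15), with Benjamini-Hochberg adjusted p under 0.05 as the threshold. The BRE fit used the 6 BRE libraries with the pair as a block, because the series states that the cells were collected in pairs at 3 times. Same-numbered BRE libraries deviated together from their group means (correlation across genes 0.756, 0.679 and 0.626 within the pairs, and -0.576 to 0.081 between them). The KO fit used the 6 Smad1/5 libraries without a block. The series names 2 parental lines, each with 1 FL and 2 KO libraries, but not which library came from which line. The fit therefore counts the 4 KO libraries as independent, although 2 came from each line. Standard errors are those implied by the fold change and its F statistic. CPM values use the TMM-scaled library sizes. The series calls the samples biological replicates, but does not describe separate cultures, so the p-values measure the spread between these libraries. KO replicates 3 and 4 were the most alike pair (median chi-square of 1.40 per gene), followed by KO replicates 1 and 2 (3.25). Replicates 1 or 2 against 3 or 4 gave 5.65 to 6.29. Replicates 3 and 4 were counted as separate because the series lists them so, and the values cannot show whether they came from 1 culture.

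Before the data were examined, 28 gene lists were fixed, with 490 genes, 11 of which matched no gene in the table. Each list was tested with camera in limma 3.58.1 with a preset correlation of 0.01, beside an estimated correlation and fry, with Benjamini-Hochberg adjustment over 27 lists of at least 3 tested genes per comparison. Also fixed beforehand was the rule for named genes. It takes the 6 largest rises and the 6 largest falls among called genes with a mean log2 CPM of at least 1 that moved the same way in every pair (BRE) or did not overlap between the groups (KO), without predicted or unnamed genes, pseudogenes and all but the first of a near-identical family. It adds up to 3 called genes of each of the 8 lists with the most calls, up to 3 of any other list whose count is given, and 14 genes of BMP signalling and pluripotency in any case. Mbd3, Flt1 as an endothelial marker and other members named beyond this rule were chosen after their values were seen.

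The test was tried on simulated counts with the libraries' fitted means and trended dispersions and 200 changed genes. The counts were drawn independently, without gene-specific dispersion, correlation between genes or a length trend between the reporter groups. The rates therefore hold for that setting and need not hold for these data. In the BRE comparison (15235 genes), edgeR recovered 44% of the genes changed 1.25-fold, 74% at 1.5-fold, 88% at 2-fold and 98% at 4-fold, and 2.6% of its calls were false. In the KO comparison (15612 genes), it recovered 0%, 42%, 70% and 90%, with 2.9% false. DESeq2 made 2.2% false calls in the BRE and 13.8% in the KO comparison, and limma, run on simulated TPM, 4.5% and 3.1%.

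Alternatives were DESeq2 1.42.0, RLE scaling, no count filter, a filter at 1 CPM, all 12 libraries in 1 fit, a test against a 1.5-fold change, limma on log2(TPM + 1) and log2(TPM + 0.1) with and without a filter at a mean TPM of 1, the fit without the block or with the replicate number as a block, and each pair or library left out. Alternatives added after seeing the data were offsets for each library's trend with exon length and GC content (loess, span 0.5), protein-coding genes only, and each possible assignment of the KO libraries to the parental lines. Overlaps of calls were tested with Fisher's exact test, 2-sided.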

Results

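Gene expression in mouse embryonic stem cells was measured by total RNA sequencing in 12 libraries from 2 experiments on BMP signalling, the pathway in which bone morphogenetic proteins activate the transcription factors SMAD1 and SMAD5. The first experiment used a reporter line that makes GFP under the control of a BMP response element (BRE). It was grown in serum and LIF on feeder cells and sorted by flow cytometry on the surface antigen SSEA1 and on GFP. There were 3 BRE-negative and 3 BRE-positive libraries, collected as pairs at 3 times. The second experiment set cells with floxed Smad1 and Smad5 alleles (FL, 2 libraries) against cells in which both genes had been deleted (KO, 4 libraries), grown in LIF with the 2i inhibitors on gelatin. The total per library was 29804485 to 35044852 counts in BRE-negative and 25862573 to 37079106 in BRE-positive cells. In FL it was 33272807 and 35736653, and in KO 30117843 to 37319846. The mitochondrial ribosomal RNA mt-Rnr2 alone took between 10.05% and 14.32% of a library.

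The first comparison asked which genes differ between cells with and without an active BMP reporter in the same culture. BRE-positive cells held more Sh3rf2, Hmga2 and Neat1 RNA and less Dppa3, Rhox5, Acta2 and Dnmt3b RNA than the BRE-negative cells collected with them. Acta2 is also a feeder fibroblast marker, at 3.28 CPM in the BRE libraries and 0.035 CPM in the Smad1/5 libraries, grown on gelatin. Sh3rf2, which encodes a protein with RING finger and SH3 domains, was 2.59-fold higher, at 1.32 ± 0.67 CPM in BRE-negative and 3.6 ± 2.4 CPM in BRE-positive cells (SD, n = 3 each, log2 fold change 1.37 ± 0.22, SE, edgeR adjusted p = 0.0045). Dppa3, which encodes the maternal factor Stella, was 2.02-fold lower, at 5.96 ± 4.75 and 2.94 ± 2.45 CPM (SD, n = 3 each, log2 fold change -1.01 ± 0.15, SE, edgeR adjusted p = 0.0036). Dnmt3b, a de novo DNA methyltransferase, stood at 121 ± 47.4 and 96.1 ± 34.7 CPM (SD, n = 3 each, log2 fold change -0.32 ± 0.06, SE, edgeR adjusted p = 0.0090). Pou5f1, Sox2 and Nanog, the central pluripotency factors, did not pass the test.

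Across all genes, edgeR's quasi-likelihood test with the pair as a block called 459 of 15435 genes, 302 higher and 157 lower in BRE-positive cells. All 459 moved the same way in the 3 pairs, as did 39.9% of all genes tested, against 25% by chance. The changes were small. The median size among the called genes was 0.32 on the log2 scale, and 11 genes were over 2-fold higher and 7 over 2-fold lower.

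Other large rises were those of Neat1, the long noncoding RNA of paraspeckles (1.77-fold, log2 fold change 0.82 ± 0.13, SE), and Hmga2, which encodes an architectural chromatin protein (1.72-fold, 0.78 ± 0.12). Cd74, the invariant chain of MHC class II, was 1.75-fold higher (0.81 ± 0.15), F5, coagulation factor V, 1.81-fold (0.86 ± 0.17) and the kinase gene Ikbke 1.71-fold (0.78 ± 0.16). The largest falls included Acta2, smooth muscle actin and a feeder fibroblast marker (2.18-fold, -1.12 ± 0.17), and the X-linked homeobox gene Rhox5 (2.17-fold, -1.12 ± 0.15). Lgals9, which encodes a galectin, was 1.97-fold lower (-0.97 ± 0.20), with -0.58 in the fit without pair 1. The small nucleolar RNA Snora73b was also 1.97-fold lower (-0.98 ± 0.07), and Rmrp, the RNA of the endonuclease RNase MRP, 1.91-fold (-0.93 ± 0.13). The adjusted p-values of the 12 genes lay between 1.54e-05 and 0.018. Except for Snora73b, Rmrp and Neat1, they stood at 6.87 CPM or less in both groups.

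**Figure D1:**
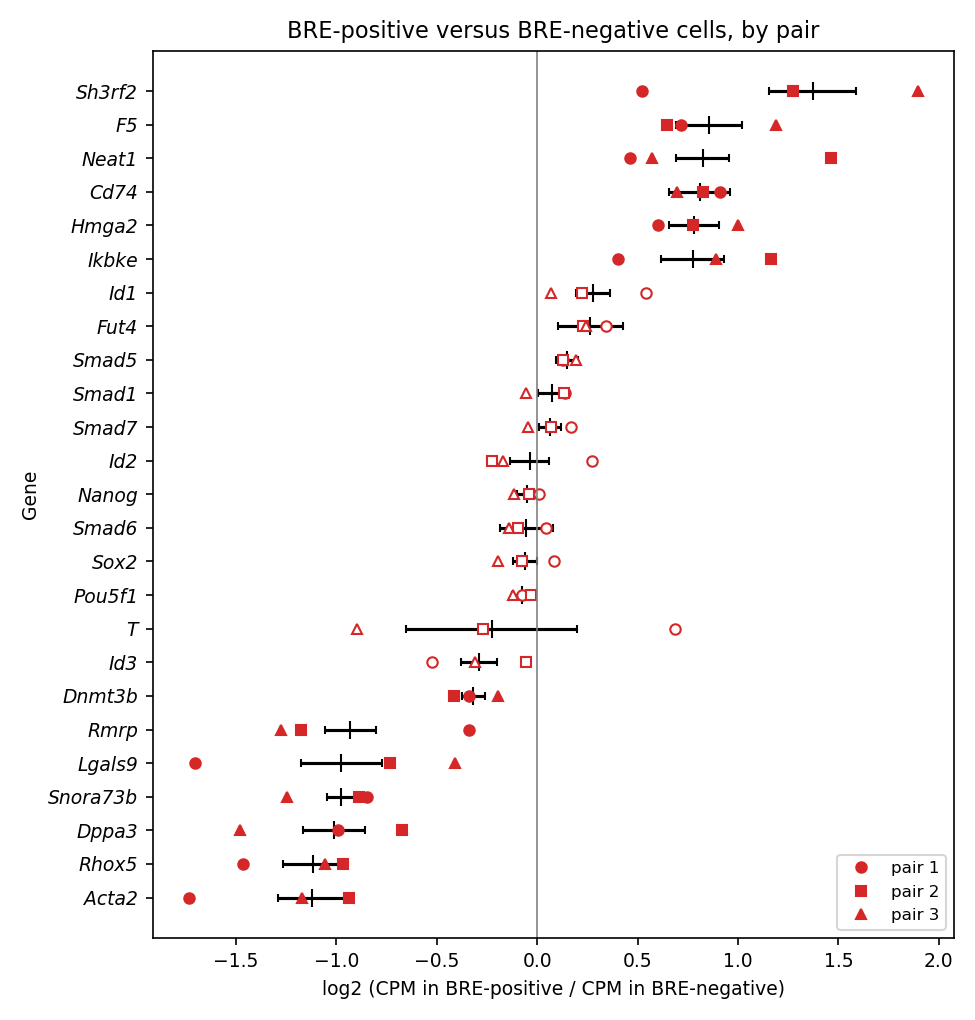
Log2 ratio of CPM (counts scaled to the library size) between BRE-positive and BRE-negative cells for named genes, 1 symbol per collected pair, with the fitted log2 fold change and its SE as a bar. Filled symbols mark genes past adjusted p 0.05, Sh3rf2 lies highest at 1.37 and Acta2 lowest at -1.12, and Pou5f1, Sox2 and Nanog lie between -0.08 and -0.05.

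Few of the genes by which BMP signalling is usually read passed a test between the reporter groups. None of 15 tested BMP-SMAD target genes passed the threshold over all genes, and adjusted over the list alone 1 was higher (Id1) and 1 lower (Id3). With offsets for transcript length and GC content, chosen after seeing the data, Id1 passed over all genes (0.34 ± 0.08, adjusted p = 0.035). The list as a set had a camera adjusted p = 0.42. Id1 stood at 23.4 ± 4.8 CPM in BRE-negative and 28.0 ± 1.3 CPM in BRE-positive cells (SD, n = 3 each), with a log2 fold change of 0.28 ± 0.08 (SE, edgeR adjusted p = 0.097) and more in the BRE-positive library in 3 of 3 pairs. Id3 had a log2 fold change of -0.29 ± 0.09 (adjusted p = 0.11), with less in the BRE-positive library in 3 of 3 pairs, and Id2 of -0.04 ± 0.09 (adjusted p = 0.87). For the inhibitory Smad6 and Smad7 the values were -0.05 ± 0.13 and 0.06 ± 0.06. For the transducers Smad1 and Smad5 they were 0.07 ± 0.07 and 0.15 ± 0.06, and the adjusted p-values of these 4 genes ran from 0.18 to 0.86. Smad9 had 3 to 10 counts per library and was not tested. Pou5f1 (-0.08 ± 0.05), Sox2 (-0.06 ± 0.06) and Nanog (-0.05 ± 0.05) had adjusted p-values from 0.46 to 0.66. The fucosyltransferase gene Fut4 had 0.27 ± 0.16 (adjusted p = 0.42). The mesoderm gene T stood at 0.39 and 0.32 CPM, with a log2 fold change of -0.23 ± 0.43.

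Of 10 tested transcripts of the mitochondrial genome, 6 were higher and 0 lower (8 and 0 adjusted over the list alone, camera adjusted p = 2.08e-15 with a preset correlation between genes, and adjusted p = 0.51 with an estimated correlation), among them mt-Nd2 (1.44-fold, log2 fold change 0.52 ± 0.05, SE), mt-Nd5 (0.42 ± 0.06) and mt-Cytb (0.36 ± 0.05). Of 20 feeder fibroblast markers, 4 were lower and 0 higher (10 and 0 adjusted over the list alone, camera adjusted p = 4.71e-08, and adjusted p = 0.51 with an estimated correlation), among them Acta2, Col1a2 (-0.48 ± 0.11) and Fbln2 (-0.41 ± 0.07). The Y-linked gene Eif2s3y, at 1.07 and 0.32 CPM, was lower as well (-1.75 ± 0.40, adjusted p = 0.030), the 1 call among 3 sex-chromosome genes (2 lower adjusted over the list alone). It had -2.09 without pair 1 and -1.13 without pair 2, where it did not pass (adjusted p = 0.20). Of 20 stress and immediate early genes, the transcription factor genes Egr2 (-0.58 ± 0.12) and Jun (-0.34 ± 0.08) and the gene Ier2 (-0.22 ± 0.05) were lower and 0 were higher (5 lower and 1 higher adjusted over the list alone, camera adjusted p = 2.58e-04, and adjusted p = 0.51 with an estimated correlation). Of 16 primed epiblast genes, Dnmt3b and Zic2 (-0.41 ± 0.09) were lower and 0 were higher (3 and 0 adjusted over the list alone, camera adjusted p = 0.012, and adjusted p = 0.51 with an estimated correlation). None of these 4 set calls held with an estimated correlation.

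The other lists did not pass as sets (camera adjusted p = 0.054 to 0.92), and their called members were few. Of 20 naive pluripotency genes, Jam2 rose (0.48 ± 0.06) and Dppa3 fell (2 and 2 adjusted over the list alone). Of 22 genes of the DNA methylation machinery, Tet1 (0.25 ± 0.05) and Zfp57, a factor that keeps methylation at imprinted loci (0.24 ± 0.05), were higher. Dnmt3b and Mbd3 were lower (4 higher and 5 lower adjusted over the list alone). For these 2 lists the median, the mean and the direction of the set test did not share a sign. Of 17 FGF-ERK targets, Spry2 was higher and Ccnd1 lower (3 and 4 adjusted over the list alone), and of 30 imprinted genes Plagl1 was higher and Peg3 lower (2 and 2). Ccnd1 was also the 1 call among 14 WNT targets (1 higher and 3 lower adjusted over the list alone) and 20 cell cycle genes (0 and 1). Single genes were lower among 13 NODAL-activin targets (Lefty1, -0.56 ± 0.11, 0 and 1 adjusted over the list alone), 11 trophectoderm genes (Tfap2c, -0.48 ± 0.07, 0 and 1), 9 neurectoderm genes (Tubb3, 0 and 2) and 20 cell adhesion genes (Vim, 1 and 3). Single genes were higher among 18 p53 targets (Trp53inp1, 6 and 0 adjusted over the list alone) and 19 glycolysis genes (Pfkp, 1 and 3). No tested member passed among BMP ligands and receptors (19), core pluripotency (11), mesoderm (10), endoderm (19), germline (17), endothelial (9), blood (8), cholesterol synthesis (19) and HOX genes (3). Adjusted over the list alone, 1 core pluripotency gene was higher and 1 lower and 1 endoderm gene was higher. A single member of the 2-cell-like list was tested and did not pass. The calls of Tet1, Zfp57, Ier2, Zic2, Spry2, Ccnd1, Peg3, Plagl1, Pfkp and Tubb3 each ended in 2 of 3 fits that left out 1 pair, and those of F5, Vim and Trp53inp1 in 1 of 3. Jun (-0.46 to -0.21) and Lefty1 (-0.70 to -0.32) kept their calls, with changes that depended on the pair left out. With the offsets, Tet1 had 0.12 ± 0.04 (adjusted p = 0.16), Ier2 -0.14 ± 0.04 (adjusted p = 0.0996), Tubb3 -0.16 ± 0.05 (from -0.23 ± 0.06, adjusted p = 0.074) and Trp53inp1 0.17 ± 0.05 (from 0.26 ± 0.06, adjusted p = 0.061).

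The calls went with transcript length. Among 13640 protein-coding genes, the log2 fold change correlated with exon length across genes, which are not independent replicates (Spearman's rho 0.271). Genes of 7.61 kb and longer held 179 higher and 7 lower calls, against 12 and 64 for genes of up to 2.46 kb. Without the pair as a block, edgeR called 0 genes (343 with an unadjusted p under 0.05, against 2817 with the block). It also called 0 with all 12 libraries in 1 fit (1361), and limma 0 on log2(TPM + 1) (2679), while DESeq2 with the block called 323. The count was 2225 without pair 1 and 200 without pair 3.

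**Figure D2:**
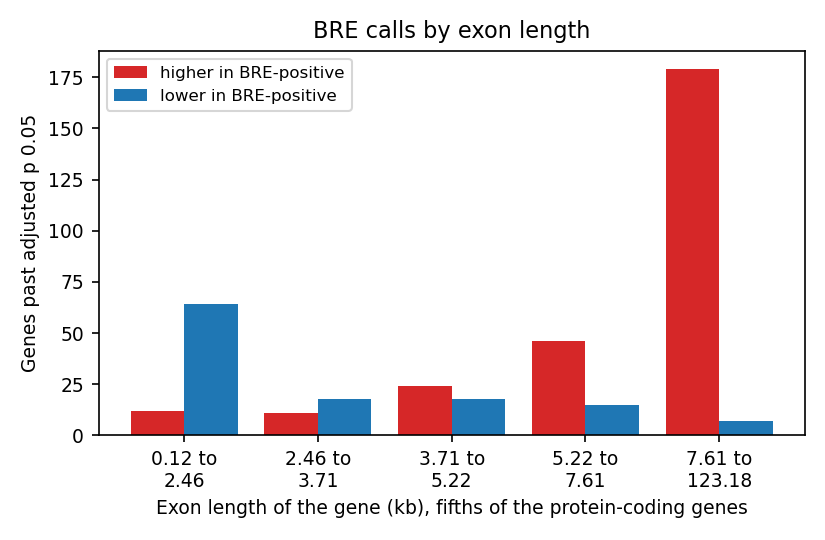
Number of protein-coding genes past adjusted p 0.05 between BRE-positive and BRE-negative cells, in 5 equal groups of genes by exon length in kb. The group of the longest genes, from 7.61 kb, holds 179 genes that are higher and 7 that are lower, and the group of the shortest, up to 2.46 kb, 12 and 64.

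The second comparison asked how deletion of Smad1 and Smad5 changes the transcriptome under 2i and LIF. The targeted genes come first. Smad1 (ENSMUSG00000031681, chromosome 8, 79338395 to 79399518, mm10) had 643 and 665 counts in the FL libraries and 427, 619, 489 and 373 in KO replicates 1 to 4. That was 18.5 ± 0.69 CPM in FL (SD, n = 2) and 14.4 ± 2.1 CPM in KO (SD, n = 4), a log2 fold change of -0.36 ± 0.14 (SE, edgeR adjusted p = 0.19). With a block for parental line, chosen after seeing the data, Smad1 passed in 1 of 6 possible assignments of libraries to lines, FL 1 with KO 1 and 2 (-0.37, adjusted p = 0.046). Smad5 (ENSMUSG00000021540, chromosome 13, 56703010 to 56742377, mm10) had 1136 and 1153 counts in FL and 880, 893, 1176 and 1046 in KO. That was 32.3 ± 1.6 and 30.4 ± 4.1 CPM, a log2 fold change of -0.09 ± 0.13 (edgeR adjusted p = 0.72). The deleted part of each gene is not given in the sources used here, and counts outside a deleted part do not show a deletion, so these values neither check nor contradict the genotype labels.

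In the libraries labelled KO, Nanog and Prdm14 were lower and Dnmt3b and Dnmt3l higher than in FL. Of 15 markers of the 2-cell-like state, 13 were lower, and 5 of 17 p53 targets were higher, with both set calls lost under an estimated correlation. Nanog was 1.52-fold lower, at 632 ± 12.8 CPM in FL and 417 ± 11.8 CPM in KO (SD, n = 2 and 4, log2 fold change -0.60 ± 0.06, SE, edgeR adjusted p = 0.0061). Pou5f1 (0.05 ± 0.07, adjusted p = 0.70) and Sox2 (-0.13 ± 0.07, adjusted p = 0.32) did not pass the test. Dnmt3b was 1.73-fold higher, at 286 ± 29.2 and 495 ± 97.5 CPM (0.79 ± 0.18, edgeR adjusted p = 0.045), and missed the threshold in 5 of 6 fits that left out 1 library (log2 fold change 0.69 to 0.90), as did Dnmt3l (0.61 to 0.86).

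In all, edgeR called 801 of 15933 genes, 294 higher and 507 lower in KO. The groups did not overlap for any of the 801, nor for 34.6% of all genes tested, against 13.3% by chance. Changes of over 2-fold were 49 higher and 338 lower.

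**Figure D3:**
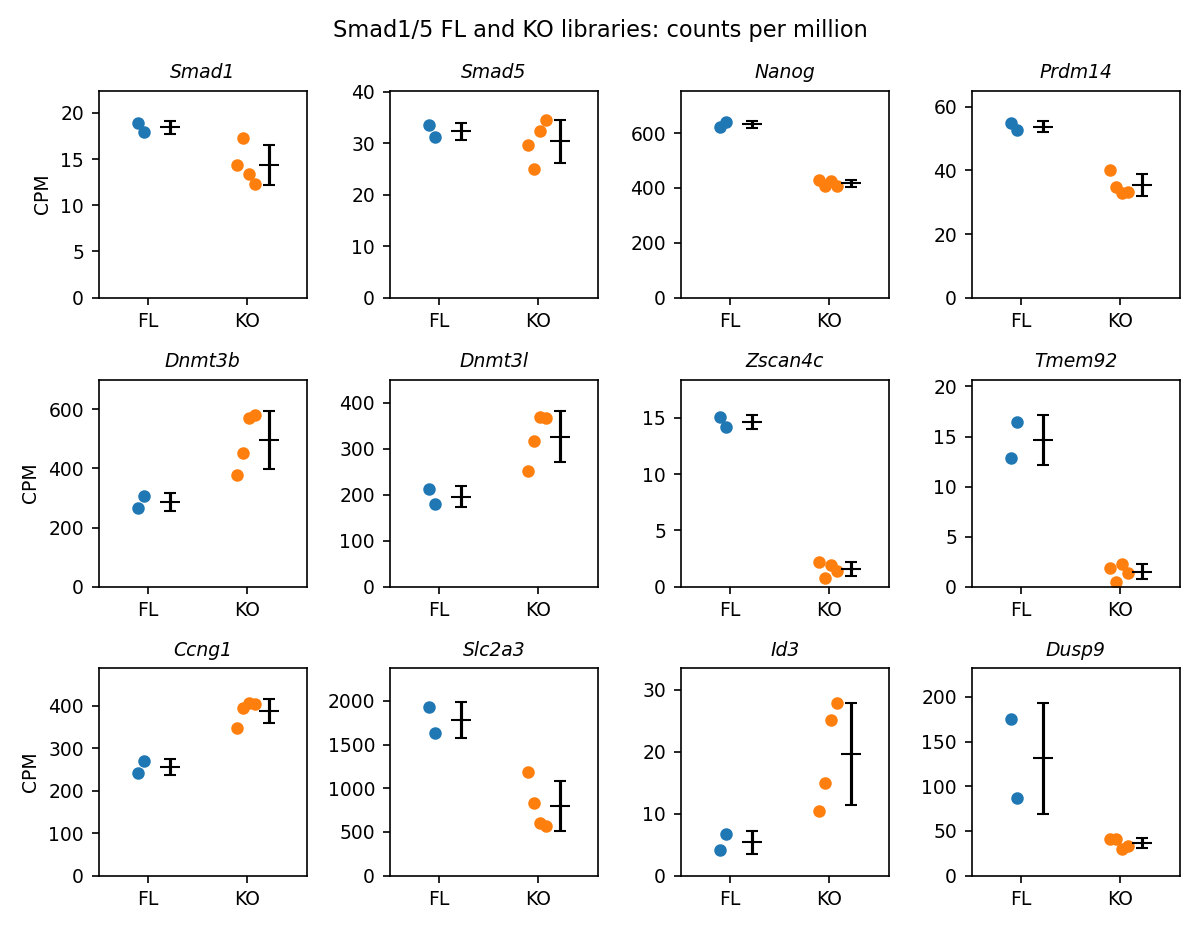
CPM of 12 genes in the 2 FL and 4 KO libraries, 1 point per library, with the mean and SD of each group as a bar beside the points. Nanog lies at 632 CPM on average in FL and 417 CPM in KO, and Zscan4c at 14.6 and 1.59 CPM.

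Predicted genes, pseudogenes and genes with a mean log2 CPM under 1 were left out of the ranking, as were further copies of near-identical families. The largest rises were those of Eya1, a transcriptional coactivator and phosphatase of organ development (5.40-fold, log2 fold change 2.43 ± 0.28, SE), and Trh, the precursor of thyrotropin-releasing hormone (5.10-fold, 2.35 ± 0.49). They were followed by Id3 (3.62-fold, 1.86 ± 0.42), the inflammasome gene Nlrc4 (3.36-fold, 1.75 ± 0.28), the adhesion molecule gene Mcam (3.31-fold, 1.73 ± 0.18) and Gpx2, a glutathione peroxidase (3.21-fold, 1.68 ± 0.16). The largest falls were those of Adgra2, an adhesion G protein-coupled receptor (15.7-fold, -3.98 ± 0.47), and Stra8, which is needed for entry into meiosis (13.4-fold, -3.75 ± 0.33). Stra8 stood at 9.39 ± 4.06 CPM in FL and 0.69 ± 0.22 CPM in KO. Zscan4b (10.7-fold, -3.43 ± 0.38), BC080695 (10.6-fold, -3.41 ± 0.39), Tmem92 (9.69-fold, -3.28 ± 0.42) and the neuroligin gene Nlgn1 (9.43-fold, -3.24 ± 0.46) came next.

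Genes of the BMP pathway moved in both directions in KO. Of 15 tested BMP-SMAD target genes, Id3 and Fst, which encodes follistatin (1.68 ± 0.27), were higher. Dusp9 (-1.85 ± 0.24) and Msx2 (-1.93 ± 0.39, at 0.76 CPM in FL) were lower (2 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.89). Id3 stood at 4.10 and 6.70 CPM in FL and at 10.5, 14.9, 25.1 and 27.8 CPM in KO (edgeR adjusted p = 0.049). It missed the threshold in 5 of 6 fits that left out 1 library (log2 fold change 1.55 to 2.24), and Msx2 in 6 of 6 (-2.19 to -1.79). Id1 (0.32 ± 0.16, adjusted p = 0.28), Id2 (0.28 ± 0.27), Smad6 (-0.76 ± 0.24, adjusted p = 0.11), Smad7 (0.23 ± 0.16) and Smad9 (-0.21 ± 0.53) did not pass. With the line block that puts FL 1 with KO 1 and 2, chosen after seeing the data, Smad6 and Smad7 passed (edgeR adjusted p = 0.035 and 0.040). Over all 24 alternatives, Smad6 passed in 3 and Smad7 in 1. Bmp4 was the 1 called member of 18 BMP ligands and receptors (0.54 ± 0.12, 1 higher and 1 lower adjusted over the list alone). Of 13 NODAL-activin targets, Bmp4 was higher and Skil (-0.56 ± 0.12) and Gsc lower (3 and 3 adjusted over the list alone). With 1 library left out, Bmp4 missed the threshold in 5 of 6 fits, Skil in 6 and Gsc in 4.

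Among 20 naive pluripotency genes, Nanog and Prdm14 (1.52-fold, -0.61 ± 0.10) fell and 0 rose (6 lower and 3 higher adjusted over the list alone, camera adjusted p = 0.044, and adjusted p = 0.69 with an estimated correlation). Of 11 core pluripotency genes, 2 were higher, among them Utf1 (0.76 ± 0.12), and 1 was lower, Dppa2 (-0.55 ± 0.11), which missed the threshold in 6 of 6 fits with 1 library left out (3 and 1 adjusted over the list alone). Of 17 primed epiblast genes, Dnmt3b and Sox11 (0.91 ± 0.20) were higher (3 higher and 1 lower adjusted over the list alone). In the DNA methylation machinery (21 tested), Dnmt3b and its cofactor Dnmt3l (1.67-fold, 0.74 ± 0.16) were higher. The demethylation factors Tet2 (1.68-fold, -0.75 ± 0.15) and Gadd45b (2.39-fold, -1.26 ± 0.11) were lower (2 and 2 adjusted over the list alone, camera adjusted p = 0.85). Of 27 imprinted genes, the noncoding RNAs Meg3 (0.82 ± 0.17) and Rian (0.72 ± 0.13), of 1 locus on chromosome 12, were higher and Peg12 (-1.59 ± 0.20) was lower (3 and 3 adjusted over the list alone).

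Of 15 tested members of the 2-cell-like list, genes that mark a rare totipotent-like state of these cultures, 13 fell and 0 rose (14 and 0 adjusted over the list alone). As a set they had a camera adjusted p = 5.02e-31, and an adjusted p = 0.49 with an estimated correlation. With fry they had an adjusted p = 0.0476. Zscan4c (chromosome 7, 11005745 to 11010547, mm10) stood at 14.6 ± 0.66 CPM in FL and 1.59 ± 0.62 CPM in KO (9.24-fold, -3.21 ± 0.31), and Zscan4f at 3.89 ± 0.08 and 0.49 ± 0.23 CPM (-3.01 ± 0.37). The Zscan4, Tcstv and Usp17l members are near-identical copies, and which copy a count belongs to is uncertain. Camera called germline genes lower as a set (adjusted p = 4.19e-04, and adjusted p = 0.49 with an estimated correlation), with 1 higher and 3 lower of 20 (1 and 5 adjusted over the list alone). Ddx4, the germ cell RNA helicase (1.89-fold, -0.92 ± 0.17), Taf7l (-0.95 ± 0.15) and Piwil2 (-0.57 ± 0.13) were lower, and Prdm1, chosen after its value was seen, was higher.

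Of 17 p53 targets, 5 were higher and 0 lower (10 and 0 adjusted over the list alone, camera adjusted p = 1.52e-08, and adjusted p = 0.49 with an estimated correlation). Among them were the cyclin gene Ccng1 (1.52-fold, 0.60 ± 0.09), Eda2r (0.47 ± 0.06) and the apoptosis nuclease gene Aen (0.43 ± 0.08), and all 17 fold changes were above 0. Of 19 glycolysis genes, 2 were lower and 0 higher (10 and 1 adjusted over the list alone, camera adjusted p = 1.71e-04, and adjusted p = 0.69 with an estimated correlation). The glucose transporter gene Slc2a3 stood at 1781 ± 208 CPM in FL and 798 ± 287 CPM in KO (2.23-fold, -1.16 ± 0.27), and Ldha, lactate dehydrogenase A, was 1.53-fold lower (-0.61 ± 0.14). Both calls ended in 5 of 6 fits that left out 1 library. Camera with a preset correlation also called mesoderm and primitive streak genes lower (Gsc and Flt1 of 13, 0 higher and 3 lower adjusted over the list alone, adjusted p = 0.043, and adjusted p = 0.49 with an estimated correlation). Both were at low levels, Gsc at 1.07 CPM in FL and 0.31 CPM in KO, and Flt1 at 2.10 and 0.33 CPM. Camera called cholesterol synthesis genes lower, with 0 of 19 past the threshold (adjusted p = 0.044, and adjusted p = 0.75 with an estimated correlation). Mitochondrial RNAs were called higher, with 0 of 9 past it (adjusted p = 0.018, and adjusted p = 0.69 with an estimated correlation). FGF-ERK targets were called higher, with Myc higher and Ier3 lower of 16 (5 and 1 adjusted over the list alone, adjusted p = 0.044, and adjusted p = 0.625 with an estimated correlation). None of the 9 set calls held with an estimated correlation.

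The remaining lists did not pass as sets (camera adjusted p = 0.083 to 0.89). Called members were Itga5 and Itgb3 (lower) and Cldn6 (higher) of 19 cell adhesion genes (4 higher and 2 lower adjusted over the list alone) and Btg2 (higher) of 19 immediate early genes (1 and 0). Loxl1 (at 0.88 CPM in FL) was lower of 11 feeder markers, Flt1 of 9 endothelial genes and Hoxb4 (at 0.57 CPM in FL) of 4 HOX genes, each also the 1 call adjusted over the list alone. No tested member was called among endoderm (19), neurectoderm (9), trophectoderm (12), WNT target (15), cell cycle (20), blood (4) and sex-chromosome (1) genes. Adjusted over the list alone, 1 neurectoderm gene was lower. The median, the mean and the direction of the set test did not share a sign for the primed epiblast, DNA methylation, WNT target, imprinted, endothelial and cell adhesion lists. T had a log2 fold change of -0.49 ± 0.49, and Fut4, with 4 to 15 counts per library, was not tested.

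**Figure D4:**
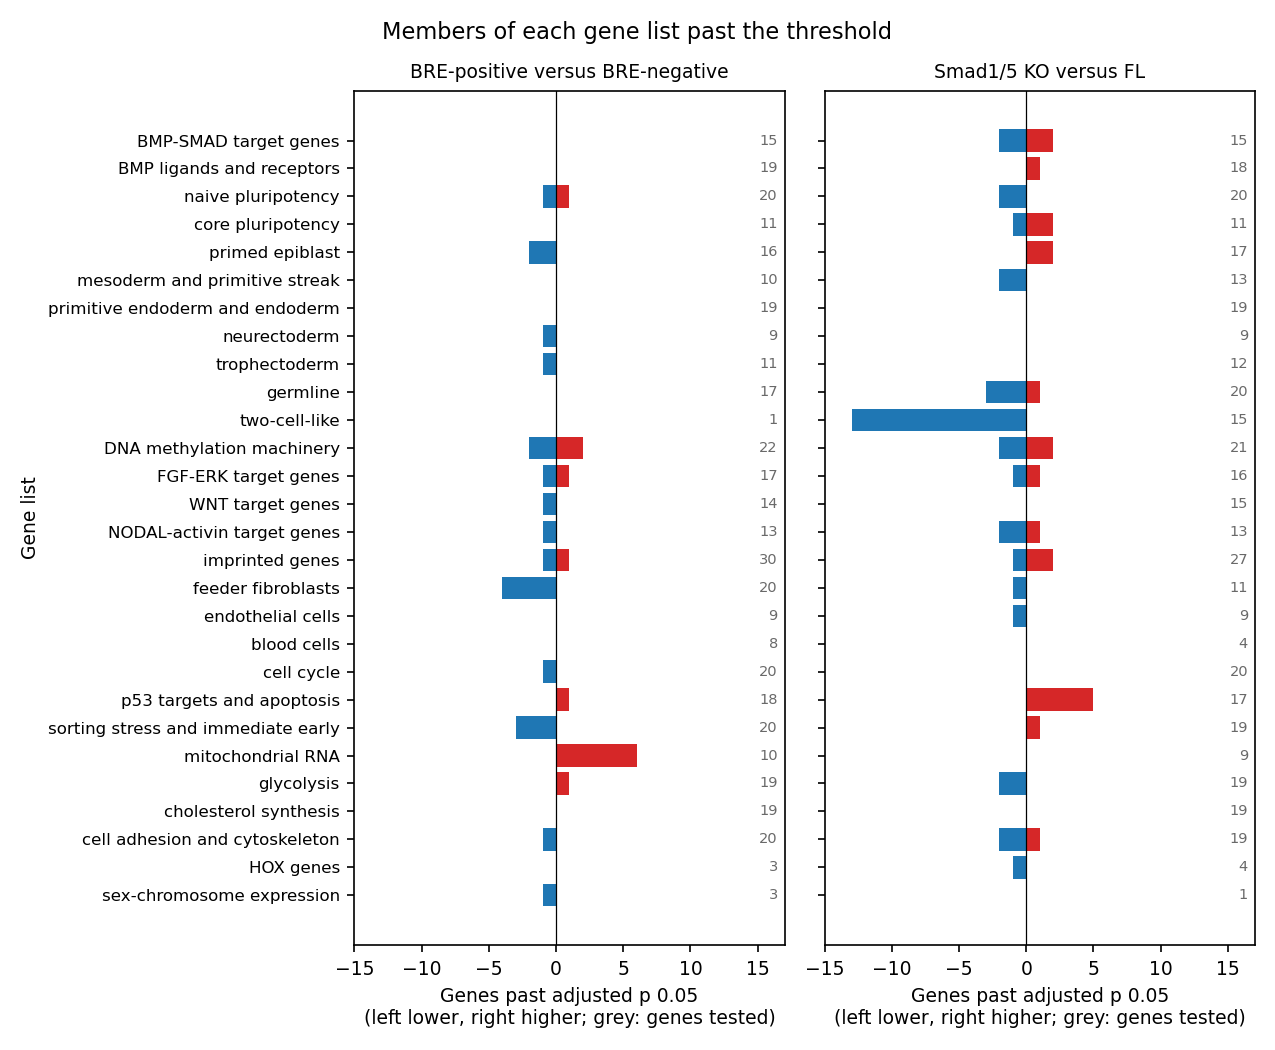
Number of genes past adjusted p 0.05 in each gene list, lower to the left and higher to the right of 0, in both comparisons, with the number of genes tested in grey. The 2-cell-like list has 13 lower genes of 15 tested in KO, and the mitochondrial RNA list 6 higher genes of 10 tested in BRE-positive cells.

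The count of KO calls by edgeR was 0 without FL replicate 1 (1948 with an unadjusted p under 0.05), 142 without FL replicate 2, 236 without KO replicate 3 and 215 without KO replicate 4, and with all libraries DESeq2 called 1498 and limma on log2(TPM + 1) 198. The calls of Aen, Piwil2, Meg3, Sox11, Myc, Ier3, Flt1, Loxl1, Cldn6 and Itga5 also ended in 5 of 6 fits that left out 1 library, that of Hoxb4 in 6, those of Trh, Ddx4, Tet2, Rian, Btg2 and Itgb3 in 4, and those of Nlrc4, Fst, Utf1 and Taf7l in 3. The series names 2 parental lines, each with 1 FL and 2 KO libraries, but not which library came from which line. With the line as a block, the count ranged from 250 to 2927 over the 6 possible assignments, chosen after seeing the data. Assignments that kept the most alike KO libraries together, 1 with 2 and 3 with 4, gave 2927 (FL 1 with KO 1 and 2) and 498 (FL 1 with KO 3 and 4). Those that mixed them gave 250 to 419.

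Whether genes that differ between the reporter groups also move on deletion of Smad1 and Smad5 was asked over the 14587 genes tested in both comparisons, which share no library. No overlap differed from that of independent lists by Fisher's exact test over genes. The comparisons also differ in cell line, medium and feeder cells, and the BRE calls leaned towards long genes. A lack of overlap therefore does not show that genes of the reporter groups are unaffected by the deletion. Of 300 genes higher in BRE-positive cells, 7 were higher in KO (5.94 expected, odds ratio 1.19, 95% interval 0.469 to 2.51, Fisher's exact p = 0.67), among them Eya1 and Trp53inp1. A further 5 were lower in KO (7.82 expected, odds ratio 0.629, 0.201 to 1.5, Fisher's exact p = 0.46). Of 150 genes lower in BRE-positive cells, 4 were higher in KO (2.97 expected, odds ratio 1.36, 0.363 to 3.6, Fisher's exact p = 0.55) and 1 was lower (3.91 expected, odds ratio 0.249, 0.00625 to 1.42, Fisher's exact p = 0.19). All 4 adjusted p-values were 0.67. Dnmt3b was among the 4, with Amotl2, Ntn1 and Tufm. The 5 were Megf11, Rhobtb1, Srgap1, Trpa1 and Zc3hav1, and the 1 was Serpinf1. Other than Dnmt3b, the names in these groups of 5, 4 and 1 were chosen after their values were seen. Without BRE pair 1, 53 genes were higher in both (odds ratio 2.91, adjusted p = 2.74e-09) and 17 lower in both (odds ratio 0.568, adjusted p = 0.0457). As a set in the KO comparison, the genes higher in BRE-positive cells had a median log2 fold change of 0.101 (camera p = 0.0076, and p = 0.45 with an estimated correlation). The genes lower in BRE-positive cells had a median of -0.034 (camera p = 0.995, and p = 0.998 with an estimated correlation).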

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

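The tests on feeder markers, on single-copy 2-cell-like genes and on slope differences within pairs were chosen after those results were seen. For the other tests on length, and those on other splits and on the FL libraries, the predictions were written before the results of those tests. The length and GC offsets themselves were an alternative chosen after seeing the data. In the group of 4 KO libraries, 65 values were searched for a library far from the other 3, and 2 stood out, where chance gives about 3.2. Trh stood at 372 CPM in KO replicate 1, against 128 to 149 CPM in the other 3. Rian stood at 518 CPM in KO replicate 2, against 679 to 695 CPM in the others.

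The 459 calls between BRE-positive and BRE-negative cells leaned towards long genes, and the length trend of a library also varies within a group. With offsets for each library's trend with exon length and GC content in the same blocked fit, 64.5% of the calls stayed past the threshold in the same direction, which argues against that trend as the whole cause, although the split of calls moved from 302 higher and 157 lower to 233 and 232. The slope on length was higher in the BRE-positive library of each pair, by 0.0389, 0.0362 and 0.0492 (exact sign-flip test, p = 0.25). That is the lowest p 3 pairs allow, so the test decides nothing, and variation between the libraries of a pair was not excluded, beside a difference between the reporter groups and a technical one that goes with the sort gate. The widest range of the slope within a group, 1.77 times the mean pair difference, runs across the pairs and does not decide either. The 10 possible splits of the 6 libraries cannot give a share under 0.05. The real split was the 1 with the most genes, 459. The highest of the other splits called 2, and the highest of the other splits that part all 3 pairs called 0. In the other splits, a difference shared by the pairs, whatever its cause, adds to the residual spread. Their low counts are therefore partly built in and support no cause.

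The lower fold changes of feeder fibroblast markers in BRE-positive cells are consistent with a smaller share of feeder cells in that sort, although gating on SSEA1, which fibroblasts lack, should remove feeders, and whether any passed the gate was not measured. Of the 20 tested markers, 11 were far lower in the feeder-free gelatin cultures, under 0.1 of their BRE level, and 100% of these had a log2 fold change below 0, with a median of -0.48 and a range of -1.12 to -0.22. These 11 are part of the list whose fall prompted the test, with 17 of 20 below 0, so their signs largely restate it. The most abundant, Col1a2, stood at 26.4 CPM in the BRE libraries and 0.17 CPM in the gelatin cultures. The 9 other markers stood at 0.1 of their BRE level or more in the gelatin cultures. Of these, 6 also had a log2 fold change below 0. Among the 6 was the called Fbln2 (-0.41), near that cut at 36.1 CPM in the BRE libraries and 3.87 CPM in the gelatin cultures. Thy1, Mfap5 and Pdgfrb had 0.25, 0.16 and 0.02. Mfap5 (1.66 and 1.78 CPM) and Twist1 (1.7 and 1.69 CPM) stood at like levels in both, and Twist1 had -0.13. A difference of the stem cells themselves in the feeder markers stays open, since the gelatin cultures are another line and medium. Y-linked genes lie outside the list. Ddx3y had 19, 31 and 23 counts in BRE-negative and 6, 18 and 11 in BRE-positive replicates 1 to 3. It did not pass (edgeR adjusted p = 0.0975). Uty (2, 26 and 16 against 0, 10 and 8) and Kdm5d (2, 3 and 2 against 0, 7 and 2) were not tested. Eif2s3y was lower in each pair, and the gelatin cultures had at most 1 count of each gene. Which cells these few reads came from was not tested.

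The fall of 2-cell-like genes in KO was weighed against shared reads and against a single library. The 3 members without near-identical copies, Zfp352, Tmem92 and Arg2, had a median log2 fold change of -2.94, which argues against reads shared between copies as the whole cause, although Arg2 by itself did not pass the test (-2.20 ± 0.60, SE, adjusted p = 0.080). The median CPM of the list in the lower FL library was 6.35 times that in the highest KO library, with 3.86 and 3.84 CPM in FL and 0.17 to 0.60 CPM in KO, so it was not carried by 1 FL library. Deletion of Smad1 and Smad5 and differences between cultures or clones in the share of 2-cell-like cells remain open and were not separated by a test.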

How the results depend on the processing

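The length and GC offsets, protein-coding fit and line assignments were chosen after seeing the data. Counts moved with the setting, and 0 of the 459 BRE and 801 KO calls turned their sign under any alternative that tested them. Little else was possible, since all BRE calls moved the same way in every pair and no KO call overlapped between the groups. The alternatives also reuse the same libraries, so the 0 does not test the directions. Of the 459 BRE calls, 311 were also called by DESeq2 (323 calls), 431 with RLE scaling and 398 among protein-coding genes. The count was 1010 without a count filter (more genes tested, and a larger share of lower genes: 534 higher and 476 lower), 0 with all 12 libraries in 1 fit, 1 against a 1.5-fold change (a stricter question), 0 with limma on log2(TPM + 1), 0 on log2(TPM + 0.1) and 0 without a filter on TPM. Without the pair as a block (no replicate block), the count was 0, and leaving out pairs gave 200 to 2225 (pair 1 left out, 1115 higher and 1110 lower). The length and GC offsets gave 465, 50.1% of them higher, against 65.8%.

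For the 801 KO calls, DESeq2 gave 1498, all 12 libraries in 1 fit 1819, a 1.5-fold threshold 67 (4 higher and 63 lower), limma on log2(TPM + 1) 198 (19.7% higher, against 36.7%), on log2(TPM + 0.1) 97 and without a filter on TPM 360 (8.89% higher). Leaving out libraries gave 0 to 857, and 0 came without FL replicate 1, which leaves 1 FL library assumed to vary like the KO group; there Zscan4c had -3.16 (adjusted p = 0.059), Stra8 -3.22 (0.059), Nanog -0.62 (0.063), Dnmt3b 0.69 (0.31) and Id3 1.55 (0.32), none past the threshold. The replicate number as a block on FL 1 and 2 with KO 1 and 2 gave 0 (2479 with an unadjusted p under 0.05); the numbers are not stated to pair these libraries, and their deviations correlated at -0.104. With FL 1 and KO 1 and 2, 1 and 3, 1 and 4, 2 and 3, 2 and 4, or 3 and 4 as 1 line, the line block gave 2927, 250, 325, 380, 419 and 498. The first of these, the grouping also seen on the second principal component, put Smad1 past the threshold, at -0.37 (adjusted p = 0.046). The planned block by stated line was not run, since the column names give no line. Beyond fewer genes tested or fewer libraries, the cause was not tested.

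The number of lists past the threshold was 4 (BRE) and 9 (KO), 0 and 0 with an estimated correlation, 0 and 1 with fry, and 7 for BRE without the block. The list of DNA methylation genes in BRE turned its direction far from the threshold with fry (adjusted p = 0.96) and without the block (0.955). No overlap of calls passed, and 2 of 4 did without BRE pair 1 (0 to 2 over the libraries left out). With 0 BRE calls without the block, or 0 KO calls without FL replicate 1, no overlap could be computed. The odds ratio of BRE higher with KO lower turned to 1.05 at adjusted p under 0.1 and ran from 0.724 to 1.65 over the libraries left out, and that of BRE lower with KO higher ran from 0 to 2.14.

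Genes not past the threshold turned their sign as follows. In BRE, limma on log2(TPM + 1), with and without a filter, and on log2(TPM + 0.1) gave Id2 0.0483, 0.0483 and 0.0497, Pou5f1 0.0139 in all 3, Sox2 0.0293, 0.0293 and 0.0294, Nanog 0.0407, 0.0407 and 0.0408 and Smad6 0.0217, 0.0217 and 0.0272. The TPM scaling shifted the fold changes over all genes by a median of 0.087, 0.086 and 0.09, about the size of these turns. Over the pairs left out, Id2 ran from -0.20 to 0.0418, T from -0.57 to 0.14 and Sox2 from -0.14 to 0.0074. In KO, the replicate block gave Id2 -0.0521 and Smad9 0.31, and over the libraries left out Smad7 ran from -0.0218 to 0.51 and Smad9 from -0.88 to 0.998. Genes that passed only under an alternative were, in BRE, Id1 with the offsets (0.34, adjusted p = 0.035), without a count filter (0.26, 0.026) and without pair 3 (0.38, 0.041), Id3 without a count filter (-0.30, 0.015) and without pair 2 (-0.41, 0.016), and Sox2 and Smad5 without pair 1 (-0.14, 0.012, and 0.16, 0.037). In KO they were Smad6 with DESeq2 (-0.77, 0.042), with all 12 libraries in 1 fit (-0.76, 0.040) and with the first line block (-0.73, 0.035), and Smad7 with the first line block (0.24, 0.040). At these depths, genes with a mean under 1 CPM had a median SE of 0.35 (BRE) and 0.44 (KO) on the log2 scale, against 0.08 and 0.13 for the others.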

Other observations

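The class of small RNAs, its test, the offsets and the restriction of the hypoxia genes to 17 were chosen after the results were seen. Calls among small structured RNAs were all towards lower levels in BRE-positive cells, and most of the class was not called. Of 261 tested RNAs annotated as snoRNA, snRNA, scaRNA, ribozyme or miscellaneous RNA, 25 were called lower and 0 higher, against 132 lower and 302 higher of 15174 other genes (lower: odds ratio 12.1, 95% interval 7.39 to 19, Fisher's exact test across genes, p = 1.49e-17). The test counts RNAs of the same libraries as independent, here and in KO, so its p and interval do not measure the spread between libraries. Besides Snora73b and Rmrp, they included Rn7sk, the RNA that holds back the elongation factor P-TEFb (log2 fold change -0.73 ± 0.10, SE), Rpph1, the RNA of RNase P (-0.68 ± 0.11), and Rnu3a (-0.65 ± 0.06). Rn7sk, Rpph1 and Rmrp together took 2.57%, 1.41% and 1.59% of the counts in BRE-negative replicates 1 to 3 and 2.05%, 0.68% and 0.90% in BRE-positive ones. These RNAs are short, and the shortest protein-coding genes also held more lower calls (64) than higher ones (12). With the length and GC offsets, Rmrp went from -0.93 to -0.78 and Snora73b from -0.98 to -0.87, both still past the threshold, and differences in the recovery of short RNAs between libraries were not tested. In KO, Rn7sk had -0.21 ± 0.26, and 5 of 268 such RNAs were higher and 0 lower (8.53 lower expected, Fisher's exact test, p = 3.00e-04). There the class took 2.11% and 2.15% of the counts in FL but 2.23%, 2.22%, 1.16% and 1.39% in KO replicates 1 to 4, a wide spread within the group.

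Some genes known to be induced by low oxygen were lower in KO beyond the glycolysis list. Among those noticed, the mitochondrial kinase gene Ak4 fell by 1.58 and Fam162a by 1.10 on the log2 scale (adjusted p = 0.0061 and 0.0080). Whether hypoxia-response genes as a group were lower was then looked at in 19 other members, whose values had been computed with all genes but not looked at 1 by 1. The 19 were measured in the same libraries as the genes noticed first, so they give no independent support. Their median log2 fold change was -0.82, 17 of 19 were below 0, and 6 were called lower and 0 higher (camera p = 3.64e-10, and p = 0.061 with an estimated correlation). Of the 19, Slc2a1 and Pdk1 belong to the glycolysis list, whose fall had been seen. Without them the median of 17 genes was -0.92 (camera p = 1.48e-10, and p = 0.0438 with an estimated correlation), a choice made after the first result. Gys1 (-1.05 ± 0.16, SE), Egln1 (-0.92 ± 0.16), Ndrg1 (-1.13 ± 0.21) and Car12 (-1.84 ± 0.30) were among the 6. Members also differed within the groups. Bnip3, among the genes noticed first, stood at 164.8 and 106.8 CPM in FL and at 57.8, 78.6, 32.6 and 34 CPM in KO replicates 1 to 4. Ddit4, of the 19, stood at 87.4 and 58.8 CPM in FL and at 55.3, 55.3, 26.7 and 28.3 CPM in KO, and was not called. Oxygen and cell density at harvest are not given in the labels, so a hypoxia response that goes with the genotype was not separated from one that goes with the cultures.

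The 6 Smad1/5 libraries also parted within the groups. On the second principal component (28.0% of the variance), FL 1 and KO 1 and 2 lay at 1.3, 23.8 and 22.3, and FL 2 and KO 3 and 4 at -22.1, -12.6 and -12.7. On the first (48.8%), both FL libraries lay below the 4 KO libraries. In the BRE libraries, the first component (55.0%) held pair 1 at -32.9 and -27.5 and the other pairs at 11.4 to 18.9. The Y-linked Eif2s3y had 10, 43 and 45 counts in BRE-negative and 7, 7 and 14 in BRE-positive replicates 1 to 3, and at most 1 count in any Smad1/5 library.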
